A study of Homo sapiens with 4 samples.

How the data were processed

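The series holds 4 RNA-seq libraries of Hs944T melanoma cells, 2 with a hairpin against EHMT2 (shG9a) and 2 with a scrambled hairpin (shScr), and groups were taken from the sample labels. Per the submitters' processing notes, the authors used STAR 2.5.2, HTSeq 0.6.1 and DESeq2 (version not given) with the human genome build hg19. The gene annotation, strandedness, filters and model formula were not given in the sources used here, and without strand information reads of overlapping and antisense genes cannot be told apart. The hairpin sequences were not given in the sources used here either.

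The values came from 1 table of the authors' comparison, with 1 row per gene symbol. Per the file headers, the authors deposited the mean normalized count of each gene, a signal averaged over all libraries after division by size factors. They deposited a log2 fold change and its standard error, per the file headers. A Wald score, the fold change divided by its standard error, and a p-value with its adjusted p-value were also deposited by the authors. The deposited log2 fold changes are shrunken towards 0, since the largest standard error was 0.194 and low genes have small values. An approximate value without shrinkage was computed from a prior width of 0.389, derived from that standard error. The table gave an adjusted p for 13592 genes, those with a mean of at least 14.4. A further 6520 genes had a p-value and no adjusted p and stayed out of all counts of calls. The direction of the fold changes is not named in the table. They were turned so that EHMT2 is lower in shG9a.

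Because the table gives statistics of the comparison and no columns per sample, the design's option for a table of comparisons was used: genes were counted as changed at the authors' deposited adjusted p under 0.05, and the main counts and list tests use the deposited statistics, with no test of samples. Tests on recovered counts are added alternatives, named as limma or as an estimated correlation where the report gives them. The names in the text follow a rule fixed before the data were examined: EHMT2, EHMT1, DKK1, MITF, LEF1, AXIN2 and MYC whatever their result; the 6 rising and 6 falling genes with the largest deposited (shrunken) change and a mean of at least 100; and up to 2 rising and 2 falling members of each main list with a mean of at least 20. This gave 82 genes, some of which are not reported here, and other names are said to have been chosen after their values were seen. Before the data were examined, 22 main lists and 8 check lists (other cell types, RNA quality, handling stress and the neighbours of EHMT2) were also fixed. A list member counts as measured at a mean of at least 10. Lists with at least 5 measured members were tested against all other genes with cameraPR of limma 3.58.1 in R 4.3.3, on the deposited Wald score with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over 27 lists. Of these, 12 passed, 4 down and 8 up. Counts adjusted over the list alone used Benjamini-Hochberg adjustment of the deposited p-values of the measured members. Random lists (10000) matched on mean count in 20 bins gave percentiles for each list's median.

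Reads per library were recovered from the deposited means. The lowest means fell on 4 steps, each the value of 1 read in 1 library, and all genes of a step shared 1 sign of the fold change, which gave 2 libraries to each group under the reading of the direction. All 2475 genes with a mean above 0 and under 1 were whole-read sums of these steps, to a tolerance of 1e-06. The steps gave size factors of 1.22 and 0.84 in shG9a and 1.11 and 0.89 in shScr. Means printed to many digits then fixed the 4 whole counts of a gene. For 13647 of 13672 genes with a mean from 2 to 1700 there was a single solution near the deposited fold change, with ratios of up to 2 allowed between libraries of a group, or more for low counts. All 164 list and named genes searched with a mean from 1700 to 4000 also had 1 solution. Up to 0.115 solutions were expected by chance for a gene of that second set, with a median of 0.034. Replicate numbers of the recovered libraries are unknown. Normalized values were compared as log2(count + 1) with limma (trend), and calls were counted over 11197 genes. For named genes, list members and camera, the 164 genes above were added, so the background above a mean of 1700 held only list and named genes. The list tests were repeated with camera on these values at the preset and at an estimated correlation. With an estimated correlation camera refers to 2 residual degrees of freedom, which leaves little power. The means, SDs and per-library values of named genes come from this step, which was chosen after the data were seen.

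The scans of 3' UTRs used GENCODE 29 on GRCh38 and 10281 genes with a mean of at least 100 and a 3' UTR of at least 30 bases. The Wald score, limited to ±10, was regressed on the presence of each of 16163 heptamers, with UTR length and AU content in the model, and compared with 100 shuffles of the genes. Genes were matched by symbol. No coordinate of the authors' build hg19 is given. All p-values are two-sided. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

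The steps were tested on simulated data. For the count recovery, all 4 counts were found for 100% of 500 simulated genes, drawn at means from 2 to 1700, with 0 wrong solutions. The simulation was given the size factors. The separate search at means from 1700 to 4000, which gave the counts of MITF and DKK1, was not simulated. For limma on the shG9a and shScr libraries (11197 genes), 51% of genes changed by 0.5 and 85% of those changed by 1 on the log2 scale were called, and 3.55% of calls were unchanged genes. In 20 simulations of the list test (14120 genes), 40 of 40 shifted lists and 0 of 480 unshifted lists were called. The simulated genes varied independently, so this gives no rate of false calls for correlated genes. In the recovered counts the estimated correlation was 0.69 for the interferon genes. The heptamer scan (10281 genes) placed 20 of 20 planted heptamers first. Alternatives were other thresholds, other sets of genes for the adjustment, other settings of the list test, centring, limma on recovered counts and leaving out each library. No rows were removed from the table. Genes listed at 0 entered no test.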

Results

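RNA of Hs944T, a human melanoma cell line that carries extra copies of EHMT2, was sequenced 72 h after the cells received a lentivirus. EHMT2 encodes G9a, the enzyme that places mono- and dimethyl marks on lysine 9 of histone H3. The virus carried a short hairpin RNA against EHMT2 (shG9a, 2 libraries) or a scrambled hairpin (shScr, 2 libraries), and the labels give 3 passages for the cells. The series addresses which genes depend on EHMT2 in cells with amplified EHMT2. The authors' deposited table gave, for 26364 genes, the mean normalized read count over all 4 libraries, the log2 fold change between the groups, its standard error (SE), a Wald statistic and p-values. Of these genes, 6252 were listed at a mean of 0. Reads per library were recovered from the means, as described under the processing. The 2 shG9a libraries held approximately 23400000 and 16100000 counted reads and the 2 shScr libraries 21300000 and 17100000, and they are called the deeper and the shallower library of their group. No source used here says whether the libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

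EHMT2 was lower in shG9a, at 49.2% of its shScr level in the authors' deposited table (log2 fold change −1.02, SE 0.07, adjusted p = 7.3e-40). In the recovered counts EHMT2 stood at 1085 ± 11.2 normalized counts in shG9a and at 2271 ± 147 in shScr (mean ± SD, n = 2 each). The deposited table does not name the direction of its fold changes. They were read so that EHMT2 was lower in the cells with its hairpin, so the direction of EHMT2 is no separate check of the labels, and every direction below rests on that reading. EHMT1, which encodes GLP, the partner of G9a in its methyltransferase complex, had a deposited log2 fold change of 0.01 (SE 0.09, adjusted p = 0.97).

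Of the 13592 genes with an adjusted p in the authors' deposited table, 2591 (19.1%) passed the threshold of 0.05, of which 1550 fell and 1041 rose in shG9a. Most changes were small. The median absolute log2 fold change of the called genes was 0.35 in the deposited table, and 74 genes changed by at least 1 on the log2 scale, 41 down and 33 up.

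By the deposited, shrunken fold change, the 6 genes that rose most among those with a mean of at least 100 were CPA4, KRT81, UCA1, KRT86, KRT80 and MUC13. CPA4, a secreted carboxypeptidase, rose by 2.86 on the log2 scale (SE 0.10, adjusted p = 4.3e-185 in the authors' deposited table), from 228 ± 21.9 to 1934 ± 41.9 normalized counts in the recovered libraries (mean ± SD, n = 2 each). UCA1, a long noncoding RNA, rose by 2.23 (SE 0.15), and the mucin gene MUC13 by 1.64 (SE 0.19) in the deposited table, or by approximately 2.53 without the shrinkage of the deposited values. The keratin genes KRT81 (2.39, SE 0.08), KRT86 (1.93, SE 0.16) and KRT80 (1.79, SE 0.10) also rose. KRT81 and KRT86 are near-identical copies, so the split of reads between them is uncertain. On the same shrunken scale, which pulls less abundant genes further towards 0 and so can change ranks, the 6 genes that fell most were LOC100130370 (−1.68, SE 0.16), VGF (−1.68, SE 0.12), SERPINA3 (−1.49, SE 0.04), PRDM7 (−1.43, SE 0.14), PMEL (−1.38, SE 0.04) and DCT (−1.38, SE 0.05), all from the deposited table. VGF encodes a secreted neuropeptide precursor, SERPINA3 the acute-phase protease inhibitor alpha-1-antichymotrypsin, and PMEL and DCT melanosome proteins. SERPINA3 had a mean of 47110 normalized counts. VGF fell from 935 ± 163 normalized counts in shScr to 251 ± 20.7 in shG9a (recovered counts, mean ± SD, n = 2 each).

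**Figure D1:**
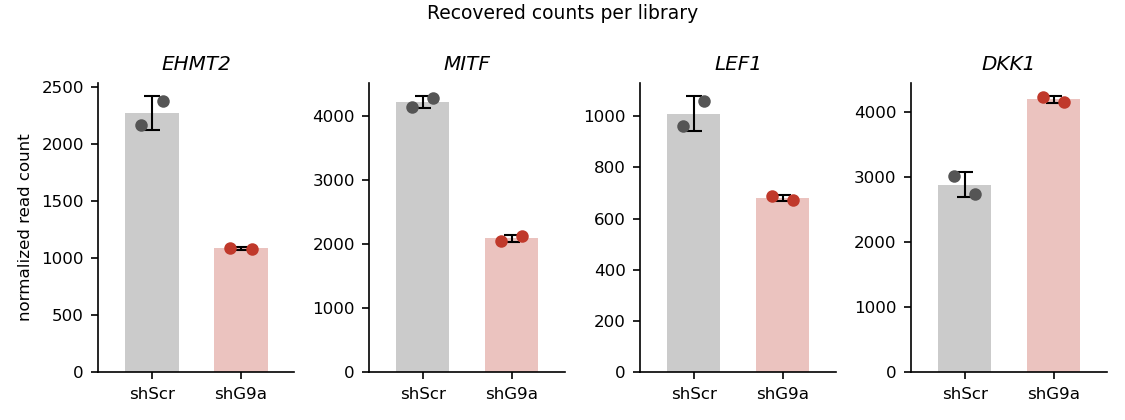
Normalized read counts recovered for each library of EHMT2, MITF, LEF1 and DKK1 in shScr and shG9a. Points are the 2 libraries of a group, bars their mean and whiskers the SD (n = 2). EHMT2 averaged 2271 in shScr and 1085 in shG9a, MITF 4213 and 2092, LEF1 1009 and 681, and DKK1 2877 and 4186.

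DKK1, a secreted inhibitor of WNT signalling and a gene the study is known to address, rose by 0.53 (SE 0.06, adjusted p = 2.4e-17 in the authors' deposited table), a 1.44-fold increase. In the recovered counts DKK1 went from 2877 ± 192 in shScr to 4186 ± 47.6 in shG9a (mean ± SD, n = 2 each). Of 7 measured WNT antagonists and DKK receptors, 3 rose and 1 fell. DKK1, IGFBP4 (0.40, SE 0.11) and SFRP1 (0.25, the last named after its value was seen) rose, and KREMEN1, a receptor of DKK proteins, fell (−0.47, SE 0.07; deposited values). Adjusted over the list alone, 3 rose and 2 fell. The list as a whole did not pass the threshold (camera adjusted p = 0.37), and its median of −0.16 and its mean of 0.01 differed in sign, the test leaning up. LEF1, a transcription factor through which beta-catenin acts, fell by 0.53 in the deposited table (SE 0.09, adjusted p = 5.3e-07). MYC had a deposited log2 fold change of −0.20 (SE 0.11, adjusted p = 0.20). It passed in limma on the recovered counts, at −0.23 with adjusted p = 0.025. AXIN2, a feedback target of beta-catenin, stood at a mean of only 27.3 counts and at 0.01 (SE 0.19, adjusted p = 0.98) in the deposited table. Among 14 measured WNT targets, 4 rose and 2 fell, also when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.57). TNFRSF19 (−0.98, SE 0.06) fell along with LEF1. The transcription factor SOX9 (0.69, SE 0.19, or approximately 1.14 without shrinkage), the cyclin CCND1 (0.45, SE 0.05), TBX3 (0.45) and JAG1 (0.31) rose in the authors' deposited table, the last pair named after their values were seen. These lists were chosen with the study's interest in WNT signalling known.

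Of 23 measured genes of the histone H3 lysine 9 methylation machinery, EHMT2 included, 2 fell and 2 rose, also when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.57). SETDB2 fell (−0.38, SE 0.12), while CBX5, which encodes the heterochromatin protein HP1 alpha (0.22, SE 0.07), and ATF7IP, a partner of SETDB1 (0.20, SE 0.07), rose in the authors' deposited table.

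Melanocyte lineage genes fell together. Of 29 measured members of the list, 24 fell and 0 rose at the deposited adjusted p, and 25 fell when adjusted over the list alone (median log2 fold change −0.65). MITF, the lineage's master transcription factor, fell to 50.4% of its shScr level in the authors' deposited table (−0.99, SE 0.06, adjusted p = 1.9e-63), from 4213 ± 93.4 to 2092 ± 51.3 recovered normalized counts (mean ± SD, n = 2 each). PMEL and DCT fell further, as given above, and the pigment genes TYR (−1.33) and MLANA (−1.30), named after their values were seen, fell by similar amounts in the deposited table. The list's test gave adjusted p = 1.3e-49 with a preset correlation (camera). On the 26 members with recovered counts, without PMEL, DCT and SOX10, camera gave adjusted p = 1.9e-25 with the preset and adjusted p = 0.18 with an estimated correlation. That estimate was 2.7e-05, below the preset of 0.01, so the larger p-value reflects the 2 residual degrees of freedom of this option. The estimated-correlation values of the lists below rest on the same 2 degrees of freedom and on recovered members only. They also depend on each list's own estimate, which lay above the preset for some lists. MITF was known to be of interest to the study, so its list is not wholly independent evidence. The 3' UTRs of MITF and DCT hold the 8 bases TTTAACAA, a sequence chosen after a scan of these fold changes. In the deposited table the 862 scanned genes with this octamer had a median log2 fold change of −0.09, the lineage genes with it or either of its heptamers one of −0.997, with 10 of 10 fallen, and those without one of −0.52, with 14 of 19 fallen. Among the other genes named by the rule, IGFBP4, IFI44L, LBR, SC5D, WARS, PSAP, MAGEA10 and SLC2A1 carry the octamer, and DKK1, LEF1, MYC, CBX5, ATF7IP, SETDB2, ACAT2, STC2, BECN1, HMMR and CKS1B 1 of its heptamers. The 3' UTRs of UCA1, LOC100130370 and GAS2L3 were not searched.

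Genes of the invasive melanoma state, which is described as low in MITF and high in AXL, rose. Of 29 measured members, 21 rose and 1 fell, against 22 and 1 when adjusted over the list alone (median 0.49). The axon guidance gene SLIT2 rose by 0.94 (SE 0.12) in the authors' deposited table. AXL itself rose by 0.41 (SE 0.05) at a mean of 5843 normalized counts. EGFR rose by 0.49 (SE 0.19) at a mean of only 33.3, close to the threshold (deposited adjusted p = 0.047). Both were named after their values were seen. The matrix glycoprotein gene TNC was the 1 member that fell (−0.31, SE 0.04; deposited values). The test of the list gave adjusted p = 3.6e-20 with a preset correlation (camera) and adjusted p = 0.32 with an estimated correlation.

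Interferon-stimulated genes fell as a group. Of 46 measured members, 37 fell and 0 rose, and 39 fell when adjusted over the list alone (median −0.45). IFI44L fell by 0.88 on the log2 scale (SE 0.16, adjusted p = 6.6e-07) and the antiviral GTPase gene MX1 by 0.84 (SE 0.13, adjusted p = 5.7e-09) in the authors' deposited table. The transcription factor gene STAT2 (−0.66 in the deposited table), named after its value was seen, was among the fallen members. The list passed with a preset correlation of 0.01 (camera adjusted p = 8.2e-23). With an estimated correlation, which was 0.69 for these genes, camera gave adjusted p = 0.59. If that estimate, itself imprecise, holds, the p-value at the preset is far too small. The shScr libraries differed in these genes. IFI44L had 3180 normalized counts in the deeper and 2433 in the shallower shScr library, against 1359 and 1242 in the shG9a libraries. IFI44L also carries the octamer TTTAACAA in its 3' UTR, and interferon-stimulated genes with the octamer or a heptamer had a deposited median of −0.46 and those without one of −0.41.

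Of 18 measured genes of MHC class I antigen presentation, 9 fell and 1 rose, or 11 and 1 when adjusted over the list alone (median −0.14). NLRC5, the transactivator of MHC class I genes (−0.42, SE 0.14), and the peptide transporter gene TAP1 (−0.42, SE 0.06) fell, and the chaperone gene TAPBP rose (0.28, SE 0.06; all from the authors' deposited table). The list's camera test gave adjusted p = 1.6e-04, and adjusted p = 0.63 with an estimated correlation. With the preset correlation it gave 0.28 on the 9 members with recovered counts.

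**Figure D2:**
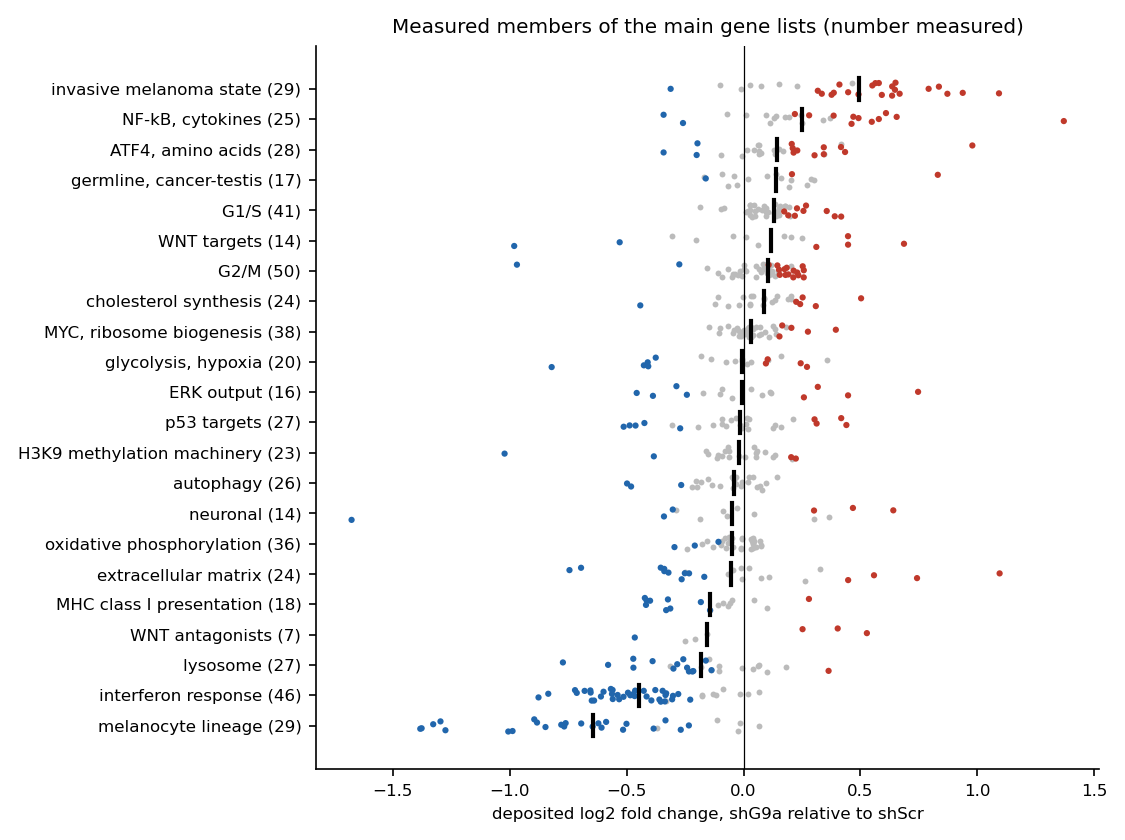
Deposited log2 fold changes (shG9a relative to shScr) of the measured members of the 22 main gene lists, with the number measured in brackets. Points are genes, red for risen, blue for fallen and grey for not past the threshold, and black bars mark medians, from −0.65 for the melanocyte lineage and −0.45 for the interferon response to 0.49 for the invasive melanoma state.

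A minority of the measured cell cycle genes rose. Of 41 measured G1/S genes, 9 rose and 0 fell (13 and 0 adjusted over the list alone; median 0.13), led by the repressor gene E2F8 (0.42, SE 0.12) and the cyclin gene CCNE2 (0.39, SE 0.08) in the authors' deposited table. The test gave adjusted p = 2.7e-04 with the preset correlation (camera) and adjusted p = 0.59 with an estimated correlation. Of 50 measured G2/M genes, 15 rose and 2 fell (16 and 2 adjusted over the list alone; median 0.10). HMMR and CKS1B each rose by 0.26 (SE 0.09 and 0.08), while GAS2L3 fell by 0.97 (SE 0.09) and the lamin B receptor gene LBR by 0.27 (SE 0.07) in the deposited table. GAS2L3 encodes a cytoskeletal linker protein of cytokinesis. The G2/M list passed with adjusted p = 0.0043 (camera), was lost at 0.10 with a preset correlation of 0.05, and had adjusted p = 0.63 with an estimated correlation. In limma on the recovered counts 12 of 35 G1/S and 12 of 39 G2/M members rose. Fewer passed without either shG9a library, as for all genes, and fewer G1/S members also without the shallower shScr library. With any 1 library left out, the median log2 difference of all recovered members lay between 0.089 and 0.14 for G1/S. For G2/M it lay between 0.076 and 0.11. HMMR lost its call without the shallower shG9a library (adjusted p = 0.068). Ribosomal protein genes, a check list for RNA quality and composition, moved the same way with a median of 0.14. All genes with a mean of at least 100 had a median of −0.01.

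Ribosomal protein genes had been listed as a check of RNA quality and library composition, and this check moved with the groups. Of 50 measured members, 36 rose and 0 fell in the authors' deposited table, with 39 risen when adjusted over the list alone (median 0.14; camera adjusted p = 1.4e-14). An estimated correlation was not computed for this list, most of whose means lie above those for which counts were recovered. Among 10000 random lists matched on transcript length and mean count, 0 had a median as high, and their median was 0.0097. Of 38 measured MYC targets of ribosome biogenesis, 5 rose and 0 fell, also when adjusted over the list alone (median 0.03). These were ODC1, the rate-limiting enzyme of polyamine synthesis (0.39, SE 0.05), the nucleolar methyltransferase gene FBL (0.28, SE 0.05), CAD (0.20), TFRC (0.17) and NOP58 (0.15) in the deposited table, the last 3 named after their values were seen. This list's adjusted p of 0.033 (camera) was lost at 0.19 with a preset correlation of 0.05 and at 0.34 when ranked by log2 fold change. It had adjusted p = 0.67 with an estimated correlation. In limma on recovered counts 4 of 22 members rose, with fewer past the threshold without either shG9a library. With any 1 library left out, the median log2 difference of the recovered members lay between −0.0040 and 0.034.

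Targets of ATF4, the transcription factor of the amino acid stress response, were split. Of 28 measured members, 10 rose and 3 fell (13 and 4 adjusted over the list alone), and the median of 0.14 was close to that of the ribosomal protein genes. The secreted glycoprotein gene STC2 rose by 0.98 (SE 0.10) and the alanyl-tRNA synthetase gene AARS by 0.43 (SE 0.05) in the authors' deposited table. The tryptophanyl-tRNA synthetase gene WARS, which interferon also induces, fell by 0.34 (SE 0.04), and SLC3A2 and SLC7A5, the 2 chains of an amino acid transporter, each fell by 0.20 (deposited values; SLC7A5 named after its value was seen). The list passed at adjusted p = 7.3e-04 (camera), with adjusted p = 0.59 with an estimated correlation. In limma on recovered counts 9 of 15 members rose, with fewer past the threshold without either shG9a library, as for all genes. With any 1 library left out, the median log2 difference of the recovered members lay between 0.17 and 0.27.

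Of 24 measured cholesterol synthesis genes, 5 rose and 1 fell, also when adjusted over the list alone. Their median was 0.09, and that of the ribosomal protein check list 0.14. The risen members included ACAT2 (0.50, SE 0.13), SQLE (0.25), DHCR7 (0.24) and INSIG1 (0.23), and the sterol desaturase gene SC5D, which carries the octamer TTTAACAA, fell (−0.44, SE 0.09) in the authors' deposited table. SQLE, DHCR7 and INSIG1 were named after their values were seen. The adjusted p of 0.039 (camera) was lost at 0.18 with a preset correlation of 0.05 and at 0.16 when ranked by log2 fold change, and was adjusted p = 0.63 with an estimated correlation. Of 22 recovered members, limma called 7 up, with fewer past the threshold without either shG9a library or without the deeper shScr library. With any 1 library left out, their median log2 difference lay between 0.048 and 0.12.

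Of 27 measured lysosomal genes, 14 fell and 1 rose (18 and 1 adjusted over the list alone; median −0.18). The cysteine protease gene CTSF fell by 0.77 (SE 0.11) and PSAP, the precursor of the saposins, by 0.58 (SE 0.03, at a mean of 67986 normalized counts) in the authors' deposited table. PSAP carries the octamer TTTAACAA, while lysosomal genes with it or a heptamer had a median of −0.14 and those without one of −0.20. The proton pump subunit gene ATP6V0D2 rose (0.36, SE 0.11; deposited value). The list passed at adjusted p = 2.0e-08 (camera), with adjusted p = 0.63 with an estimated correlation, which was 0.25 against the preset of 0.01. In limma on recovered counts 8 of 15 members fell, with fewer past the threshold whichever library was left out. With any 1 library left out, the median log2 difference of the recovered members lay between −0.18 and −0.15. Of 26 measured autophagy genes, 3 fell and 0 rose, also when adjusted over the list alone. They were WIPI1 (−0.50, SE 0.09), BECN1 (−0.48, SE 0.08) and ATG12 (−0.27, named after its value was seen) in the deposited table, and the list did not pass (camera adjusted p = 0.37). In limma on recovered counts 7 of 25 autophagy members fell, with fewer past the threshold without either shG9a library or without the deeper shScr library. With any 1 library left out, the median log2 difference of the recovered autophagy members lay between −0.088 and −0.038.

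Of 25 measured NF-kB targets and inflammatory cytokines, 11 rose, 2 fell and 12 did not pass (12 risen and 2 fallen adjusted over the list alone; median 0.25). The cytokine gene IL6 rose by 1.37 (SE 0.12, adjusted p = 3.9e-26), a 2.58-fold increase, and the chemokine gene CXCL1 by 0.65 (SE 0.16) in the authors' deposited table. IL6 went from 218 ± 3.71 to 639 ± 34.95 recovered normalized counts (mean ± SD, n = 2 each). The adhesion molecule gene ICAM1 (−0.34, SE 0.04) and the signalling adaptor gene TRAF1 (−0.26, SE 0.09) fell in the deposited table. TRAF1 lost its call without the deeper shG9a library (adjusted p = 0.064 in limma). The list passed at adjusted p = 5.6e-05 (camera), with adjusted p = 0.59 with an estimated correlation, which was 0.28 against the preset of 0.01.

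Of 16 measured genes of ERK signalling output, 4 rose and 4 fell (4 and 5 adjusted over the list alone). The receptor gene EPHA2 (0.75, SE 0.07), CCND1 (0.45, SE 0.05), FOSL1 (0.32) and DUSP5 (0.26) rose, and the feedback phosphatase gene DUSP6 (−0.46, SE 0.05), ETV5 (−0.39, SE 0.05), DUSP4 (−0.29) and PHLDA1 (−0.24) fell in the authors' deposited table. Those without an SE were named after their values were seen. The list did not pass (camera adjusted p = 0.75), and its median of −0.01 and its mean of 0.02 differed in sign, the test leaning up. Of 27 measured p53 targets, 4 rose and 5 fell (5 and 5 adjusted over the list alone; camera adjusted p = 0.97). The kinase gene PLK2 (0.44, SE 0.06) and GADD45A (0.42, SE 0.08) led the risen members, and PHLDA3 (−0.51, SE 0.06) and PLK3 (−0.49, SE 0.10) the fallen ones (deposited values). The others were MDM2 (0.31), SESN2 (0.30), TP53INP1 (−0.46), GDF15 (−0.42) and TIGAR (−0.27), named after their deposited values were seen.

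Matrix genes moved in both directions. Of 24 measured members, 4 rose and 10 fell (5 and 10 adjusted over the list alone; camera adjusted p = 0.50). The collagenase gene MMP1 rose by 1.09 (SE 0.04, adjusted p = 7.6e-160), MMP3 by 0.74 (SE 0.19, or approximately 1.48 without shrinkage), FN1 by 0.56 and LOXL2 by 0.45 in the authors' deposited table, FN1 and LOXL2 named after their values were seen. TIMP1, an inhibitor of these proteases, fell by 0.74 (SE 0.05) and the basement membrane collagen gene COL18A1 by 0.70 (SE 0.08; deposited values).

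Of 37 germline and cancer-testis genes, 17 were measured, of which 2 rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.16). The cancer-testis antigen genes MAGEC1 (0.83, SE 0.13) and MAGEA10 (0.21, SE 0.07) rose and PRAME fell (−0.16, SE 0.05) in the authors' deposited table. The list passed in camera on the recovered counts at the preset correlation (adjusted p = 0.049), with adjusted p = 0.59 with an estimated correlation. Of 14 measured neuronal genes, 3 rose and 3 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.56). BEX1 (0.64, SE 0.12) and the neurofilament genes NEFM (0.47, SE 0.11) and NEFL (0.30) rose, and L1CAM (−0.34, SE 0.09) and TUBB3 (−0.30) fell with VGF in the deposited table, NEFL and TUBB3 named after their values were seen.

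Of 20 measured genes of glycolysis and the hypoxia response, 4 rose and 5 fell, also when adjusted over the list alone (camera adjusted p = 0.24). The glucose transporter gene SLC2A1 fell by 0.82 (SE 0.07) and PFKFB4 by 0.43 (SE 0.07), as did HK2 (−0.41), ENO2 (−0.41) and SLC2A3 (−0.38), while VEGFA rose by 0.27 (SE 0.06), BNIP3 by 0.24 (SE 0.09), LDHA by 0.10 and ENO1 by 0.10 in the authors' deposited table. Those without an SE were named after their values were seen. BNIP3 lost its call without the shallower shG9a library (adjusted p = 0.062 in limma) and without the deeper shScr library (adjusted p = 0.076). Of 36 measured subunits of oxidative phosphorylation, 3 fell and 0 rose, also when adjusted over the list alone (camera adjusted p = 0.40). These were the complex I genes NDUFV2 (−0.30, SE 0.06) and NDUFV1 (−0.21, SE 0.07) and ATP5B (−0.11, named after its value was seen) in the deposited table. NDUFV1 lost its call without the deeper shG9a library (adjusted p = 0.096 in limma). Of 30 recovered members of this list limma called 5 down, 1 without the deeper and 3 without the shallower shG9a library and 7 without the deeper shScr library.

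Of 17 measured neighbours of EHMT2 on chromosome 6, 4 rose and 2 fell, also when adjusted over the list alone (median 0.10; camera adjusted p = 0.37). The complement genes CFB (−0.73) and C2 (−0.60) fell, and HSPA1B (0.37), LSM2 (0.35), VARS (0.15) and CLIC1 (0.14) rose in the authors' deposited table, all named after their values were seen. HSPA1B is a near-identical copy of HSPA1A, so its value is uncertain. Of 6 measured fibroblast markers 1 rose, COL6A3 (0.53, named after its value was seen), and 0 fell (camera adjusted p = 0.52). None of 5 keratinocyte (camera adjusted p = 0.50), 2 leukocyte and 3 endothelial markers passed at the deposited adjusted p, and 1 endothelial marker fell when adjusted over the list alone, the last 2 lists being too small for the test. Of 15 immediate-early and heat shock genes, 3 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.21). They were HSPA1B, HSPA8 (0.21) and IER2 (0.17) on one side and FOS (−0.96) on the other in the deposited table, again named after their values were seen. Genes of the mitochondrial genome had 0 rows in the table under the names searched.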

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

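Settings that use recovered counts, leave out a library or undo the shrinkage were chosen after the data were seen, and the others before the data were examined. No paired analysis was possible because the deposited table has 1 value per gene and the recovered libraries carry no replicate number. Across genes, the difference of the deeper from the shallower library in shG9a and in shScr had a correlation of 0.064. The 2591 calls became 74 when a change of at least 1 on the log2 scale was also required, and lay between 1753 and 3069 under the other planned thresholds and adjustments. Over the 11197 genes with recovered counts, the deposited table called 1565 and limma 3083, which included all 1565. Leaving out each library in turn gave 1821 to 2719, the lowest without the shallower shG9a library, and 2014 without the deeper one. With a library left out, the lone one is assumed to vary like the other group. The fold change of EHMT2 stayed between −1.13 and −0.997 in all settings run.

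Of 133 list results under planned settings, 123 kept their direction and side of the threshold. A preset correlation of 0.05 ended the calls of G2/M (0.102), MYC targets (0.194) and cholesterol synthesis (0.176), and ranking by log2 fold change ended the same 3 (0.157, 0.341 and 0.157). The rank-based test called the immediate-early genes (0.0482). It turned the direction of ERK output (0.904) and of neuronal genes (0.969), and p53 targets turned among genes with a mean of at least 100 (0.888), none of them past the threshold. In camera on recovered counts at the preset correlation, MHC class I (0.281), MYC targets (0.509) and cholesterol synthesis (0.0699) lost their calls, germline genes gained one (0.0485), and WNT antagonists (1.00 down) and neuronal genes (0.809 up) turned. Fewer members entered there. With an estimated correlation 0 lists passed in camera, and 2 lists, the melanocyte lineage and the invasive state, had an unadjusted p under 0.05. With 2 libraries per group this option of camera has only 2 residual degrees of freedom, so hardly any list could pass. That 0 passed is therefore by itself no evidence against the lists, though some lists also had estimated correlations well above the preset, as given below. The adjusted p was 0.180 for the melanocyte lineage, 0.323 for the invasive state, 0.591 for interferon, G1/S, ATF4 and NF-kB, 0.635 for MHC class I, G2/M, cholesterol and lysosome and 0.672 for MYC targets, and WNT antagonists (1.00) and neuronal genes (0.890) again turned. Among random lists matched on mean count, the medians of cancer-testis genes (percentile 99.85), EHMT2 neighbours (98.43), WNT targets (98.29) and WNT antagonists (2.24) were near the ends, though these lists did not pass in camera. MYC targets, which passed, stood at 92.55. Of the other lists that passed, the melanocyte lineage, interferon and lysosome stood at 0 and MHC class I at 0.41. Cholesterol synthesis stood at 99.68, ATF4 at 99.99, and the invasive state, G1/S, G2/M, NF-kB and ribosomal proteins at 100. With any 1 library left out, the median log2 difference of recovered members lay between −0.80 and −0.71 for the melanocyte lineage. For the invasive state it lay between 0.60 and 0.66, and for interferon between −0.57 and −0.39. That median changed sign between settings for H3K9 genes, MYC targets, p53 targets, ERK output, matrix, neuronal and fibroblast genes. The number of members limma called also changed, as for H3K9 genes, WNT targets, p53 targets, germline, matrix, neuronal, glycolysis and immediate-early genes. With 2 libraries per group the estimated correlations themselves are imprecise. Apart from these degrees of freedom, why list results changed with the ranking, the test or the set of genes was not tested.

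Of 484 values of named genes under alternatives, 476 kept their call and direction, 5 lost the call (HMMR, TRAF1, NDUFV1 and, in 2 settings, BNIP3), 1 gained one (MYC) and 2 turned without a call. Leaving out each library, EHMT1 ranged from −0.029 to 0.047 and AXIN2 from −0.082 to 0.137, both lowest without the shallower shG9a library. For 4 genes, AXIN2, SOX9, MUC13 and MMP3, the value without shrinkage was over 1.5 times the deposited one. Limma and the left-out libraries covered only 64 of the 82 named genes, since counts were not recovered above a mean of 4000. SERPINA3, PMEL, DCT, MX1 and MMP1 were among those not covered. Depth limits the low genes most, as for AXIN2 at 27.3 counts.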

Other observations

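The lists of MHC class II, glial and keratin genes and all tests on the melanocyte and interferon genes below were chosen after the results were seen, as was the octamer, which was built from the leading heptamers of the scan. The scan of 3' UTR heptamers itself was fixed before its result was seen. MHC class II genes, which melanoma cells can express, fell in shG9a. Of 14 measured members, 12 fell and 1 rose in the authors' deposited table (median −0.56). HLA-DRA fell by 0.64 (SE 0.04), the invariant chain gene CD74 by 0.55 (SE 0.04), HLA-DPB1 by 0.77 (SE 0.07) and CIITA, the transactivator of these genes, by 0.43 (SE 0.10). The thiol reductase gene IFI30 rose (0.50, SE 0.11). HLA genes are similar in sequence, and reads shared between them make single members uncertain.

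Genes of Schwann cells and myelin, which share the neural crest origin of melanocytes, fell as well. Of 15 measured members, 12 fell and 1 rose in the authors' deposited table (median −0.64), among them S100B (−1.26, SE 0.05), APOD (−1.19, SE 0.05), and the myelin genes MBP (−0.87, SE 0.07) and PMP2 (−1.35, SE 0.17). The cadherin gene CDH19 rose (0.35, SE 0.09). SOX10 and ERBB3 are also in the melanocyte list and L1CAM in the neuronal list. Of 12 measured keratin and epithelial genes, 6 rose and 1 fell in the deposited table. KRT18 (0.45, SE 0.08), KRT7 (0.83, SE 0.19) and KRT34 (0.78, SE 0.18) rose beside KRT81, KRT86 and KRT80, which led to the choice of this list, and the tight junction gene CLDN1 fell (−0.25, SE 0.05).

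The 3' UTR heptamer TTAACAA went with lower expression in shG9a (t = −10.7, against −5.55 for the lowest of 100 shuffles), which is what silencing of other transcripts through the seed of the EHMT2 hairpin may leave. It also occurs in EHMT2 transcripts, as do 5006 of the 16163 heptamers tested. As a description only, since the octamer TTTAACAA was chosen from this scan of the same fold changes, 25.6% of the 862 genes with it fell, against 14.3% of length-matched genes, up to 25.4% for other octamers of the same bases and up to 21.7% for those without either heptamer, while genes with a heptamer alone fell in 16.6% and 16.5%, against 14.4% and 14.2% of matched genes. The octamer occurs in 8 of 12 annotated EHMT2 transcripts and once in the longest. In an annotated transcript chosen separately it lies in coding exon 23 of 27 (GRCh38 chromosome 6, 31882981 to 31882988, minus strand, within GCTCCAGGAATTTAACAAGATTGAGCCT). The hairpin sequence was not given, so silencing through its seed remains a hypothesis. The excess of fallen genes with a site over length-matched genes was 142, or 9.71% of the 1462 fallen genes scanned. The matching did not cover AU content, and other octamers of the same bases had a median of medians of −0.03. The excess is therefore not a share due to the site alone. For genes higher in shG9a, a seed of the scrambled hairpin cannot be told apart from other causes, since the highest t of 5.84 passed the shuffles (5.07) but was weaker than the lowest.

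The fall of melanocyte lineage genes was set against technical explanations. Of 10000 random lists matched on mean count, 0% had a median as low, which argues against a trend with expression level. The cancer-testis genes of the same cells had a median of 0.14, at percentile 99.85 of matched lists. That argues against dilution by cells without these genes only if lower EHMT2 does not itself raise them, which was not tested. Cells of the same line low in MITF would escape this check. Octamer or heptamer sites in the lineage genes themselves are argued against as the whole cause, since members without a site had a median of −0.52, but members with one had −0.997 (10 of 10 fell, 5 of them with the octamer), so a part of their fall may come from sites. What stays open is MITF, whose own 3' UTR holds the octamer: its change of −0.99 may come from lower EHMT2 or from the hairpin acting on MITF, and the 2 cannot be told apart with these 4 libraries. A second hairpin of another sequence would separate them.

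Interferon-stimulated genes were higher in the deeper than in the shallower shScr library (median log2 value around each gene's mean 0.35 against 0.13). Without the deeper library the median difference of the recovered members was still −0.39, which argues against 1 library as the whole cause, and members without an octamer or heptamer site had a median of −0.41, against −0.46 with one, which argues against their own sites as the whole cause. The list's median of −0.45 may also reflect a different innate response to the hairpins or the virus doses. This cannot be told apart from an effect of EHMT2, because uninfected cells and further hairpins were not analysed here. Lower EHMT2 remains an open explanation that was not tested separately.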
